A study of Vitis vinifera with 4 samples.

How the data were processed

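The data were 4 degradome libraries of grape (Vitis vinifera), 1 each for fruit peel and young leaf of the cultivars Bangalore blue and Dilkhush. Per the labels' protocols, total RNA was extracted with a plant RNA column kit and libraries followed a published parallel analysis of RNA ends protocol with small changes. Nothing in the labels says from how many plants or pools the RNA came. The deposited files hold raw read counts per tag: per the file headers, each row is a sequence and its count. Tags were 20 or 21 nucleotides long. Trimming, filtering and any alignment by the authors are not given in the sources used here, nor is a genome build. The counts were not normalized, since they are whole numbers with totals that differ between libraries.

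Tags with an undetermined base were dropped, which removed 0.0672%, 0.0698%, 0.0693% and 0.0705% of reads in Bangalore blue peel and leaf and Dilkhush peel and leaf. The first 20 nucleotides of each tag were used, and counts were scaled to RPM, the share of reads on a scale of 1e6, of the remaining 6073899, 37497039, 17191299 and 35730871 reads. Tags with 1 read made up 62.2%, 52.7%, 61.4% and 57.3% of distinct tags. A floor of 3 reads corresponded to 0.494, 0.0800, 0.175 and 0.0840 RPM.

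Degradome tags name a gene only when matched to transcripts, and no genome or transcript sequence was used here. The planned counts per gene, the 13 gene lists including the flavonoid list, the cell type markers and the planned target score and transcript category were therefore not computed, and comparisons were made per tag. Ribosomal and organelle tags could not be set aside, and the origin of single tags was not tested. Tags were compared as ratios of RPM with exact conditional Clopper-Pearson intervals at 95%, for tags with at least 20 reads in the 2 libraries together, and a tag was counted when its interval lay wholly beyond 2-fold. By molecule-equivalents, tags with at least 1 in the pair were compared in the same way. Named tags were the 2 per direction and comparison whose interval bound nearest to no change was the largest. The ranking had been fixed for 10 genes per direction, and the number was reduced to 2 when tags took the place of genes.

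Sites of 32 small RNAs in 30 families were searched. Their sequences were written from general knowledge. These sequences, the ranking of named items, the minimum reads and the 2-fold limit were set before the data were examined. A slicing tag started with the exact reverse complement of nucleotides 1 to 10. It was supported with at least 5 reads, unless a tag 1 mismatch away in the same library had 15 times its reads. That ratio was set after read errors had been measured: for abundant tags with at least 1000 reads, the version with G2T (position from 1 at the tag's 5′ end) held a median of 3.32%, 3.67%, 3.67% and 3.52% of their reads in the 4 libraries. Controls were the same complements 1 to 10 nucleotides into the tag and 100 sets of shuffled miRNAs with a fixed seed. All supported sites of miR828, miR858, miR159, miR319 and the TAS3-derived small RNA were named, and for each other family the site with the highest RPM. Further sites and the R3-coding tags were named after their values were seen.

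Tags coding for at least 5 residues of the conserved R3 peptide of R2R3-MYB proteins were placed by their start. Reads per tag piled up at a preferred number per library, found as the maximum of the histogram smoothed over 5 values beyond the error tail. Reads divided by that number are called molecule-equivalents, a unit chosen after the data were seen. The tags carry no molecular identifiers, so all intervals and floors cover counting error only. A fold against a library at 0 was computed against 3 molecule-equivalents.

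The rules were tested on simulated libraries drawn from the real tags' means, with 200 tags changed 8-fold and at least 10 expected molecules each. Simulated molecules were multiplied to each library's own preferred number of reads, with an assumed spread of copies. The rates from these libraries therefore hold only if that number is the copies per molecule. By molecule-equivalents 98.5%, 97.0%, 99.0% and 98.0% of the changed tags were recovered in the comparisons of the cultivars in peel (148059 tags) and leaf (585507 tags) and of the tissues in Bangalore blue (390603 tags) and Dilkhush (375704 tags), and by reads all 200 in each. The median ratio of tags with at least 20 reads in both libraries was also taken in the simulated libraries. Of 50 slicing starts planted among 20000 random tags, the search returned 52 tags, chance matches included.

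Alternatives were another total for scaling, median-of-ratios scaling over tags with at least 20 reads in both libraries, merging of tags 1 mismatch apart, other count minimums, thinning to the smallest library, a start within 1 nucleotide, a G:U pair and other error rules. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.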

Results

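Degradome sequencing reads the 5′ ends of uncapped RNA fragments, so that an RNA cut by a small RNA leaves a pile of tags that start at the cut. The data covered 2 grape cultivars, Bangalore blue and Dilkhush, chosen for different anthocyanin levels, and 2 tissues, fruit peel and young leaf. Each of the 4 combinations had 1 library. The files listed 6077983 reads for Bangalore blue fruit peel, 37523220 for Bangalore blue young leaf, 17203217 for Dilkhush fruit peel and 35756064 for Dilkhush young leaf. The files list tags and counts and do not pair them with genes, so items are named by tag sequence and by the small RNA they complement. With 1 library per group no difference had a replicate check, no test between groups was run, and every interval below, at 95%, covers counting error only. Levels are given in RPM, reads scaled to the reads used in a library.

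Most tags were private to a library. Of 2893341 distinct 20-nt tags, 91.4% were found in 1 library and 9544 were found in all 4. Reads per tag had a preferred number that differed between libraries, 33 in Bangalore blue fruit peel, 13 in Bangalore blue young leaf, 36 in Dilkhush fruit peel and 24 in Dilkhush young leaf. Dividing reads by that number gave 184058, 2884388, 477536 and 1488786 molecule-equivalents in the same order, and the intervals of ratios for sets of tags below were computed on these smaller numbers unless reads are named. The median log2 ratio of tags with at least 20 reads in both libraries was 0.79 for Bangalore blue over Dilkhush in peel, -0.22 in leaf, and 2.16 and 0.97 for peel over leaf in Bangalore blue and Dilkhush. In simulated libraries without a difference the same medians were 0.54, -0.09, 1.41 and 0.58, so the choice of tags can shift the median. The simulated libraries shared more such tags, 54561, 235949, 77545 and 137138 against 6465, 63374, 10193 and 24499 in the data. They therefore do not measure how much of each shift in the data comes with that choice. Among tags with a mean of at least 50 RPM the medians were 1.31, -0.23, 2.92 and 0.15 in the data and 0.05, -0.01, 0.04 and 0.08 in the simulated libraries, so the comparisons with Bangalore blue peel also kept a large shift by that choice.

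**Figure D1:**
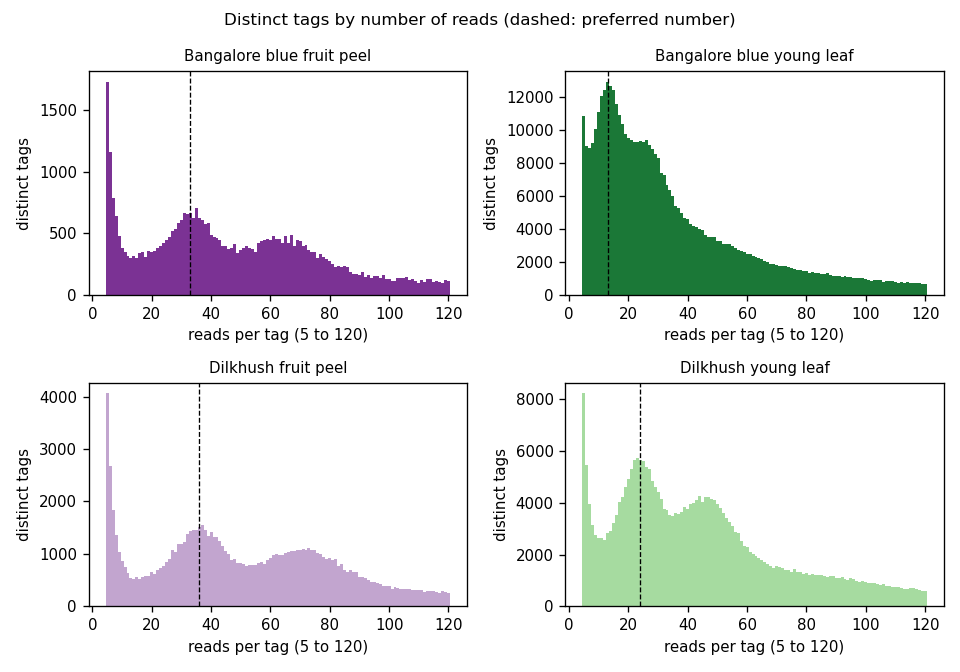
Number of distinct tags (vertical axis) against reads per tag (horizontal axis, 5 to 120 reads) in each of the 4 libraries, with the preferred number dashed at 33, 13, 36 and 24 reads. A second maximum lay at 63 reads in Bangalore blue fruit peel, 73 in Dilkhush fruit peel and 46 in Dilkhush young leaf.

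Tags starting at predicted small RNA cut positions were more frequent than tags with the same complement elsewhere. Slicing leaves a fragment that starts with the reverse complement of miRNA nucleotides 1 to 10. Supported tags of this kind, with at least 5 reads, numbered 10 in Bangalore blue fruit peel, 66 in Bangalore blue young leaf, 14 in Dilkhush fruit peel and 46 in Dilkhush young leaf. The same complements placed 1 to 10 nucleotides into the tag gave means of 2.5, 24.5, 7.0 and 14.7 tags. Shuffled miRNA sets gave means of 1.43, 14.7, 3.43 and 8.68 tags, and 0, 0, 2 and 0 of 100 sets gave as many as the real set. Of 30 families, 16 had a library where the tag start held more reads than any of the other 10 positions and at least 3 molecule-equivalents. That made 33 of 120 family and library pairs. If each of the 11 start positions were equally likely to hold the most reads, at most 10.9 would be expected on average. No spread around that number was computed.

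**Figure D2:**
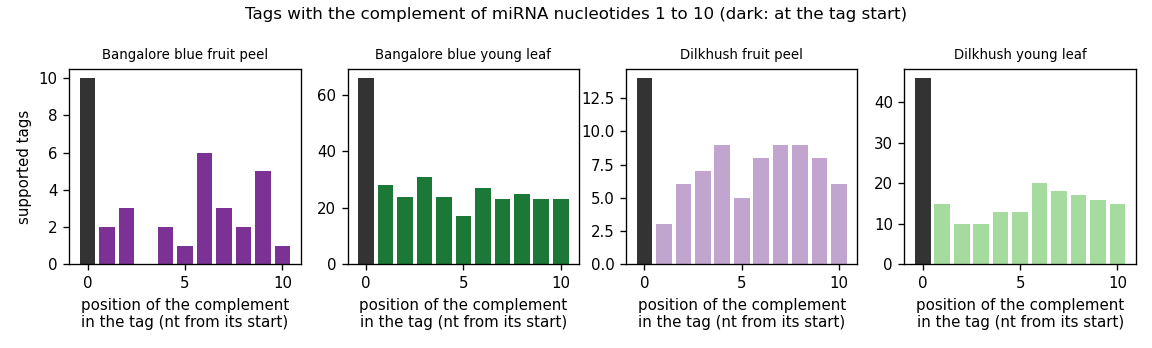
Supported tags (vertical axis) by position of the complement in the tag (horizontal axis, nucleotides from the tag start) in each library. The dark bar at 0 is the slicing position, with 10, 66, 14 and 46 tags, and the highest other bars reach 6, 31, 9 and 20.

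The tissue comparison asked how slicing tags differed between fruit peel and young leaf of the same cultivar. In Bangalore blue, tags at the cut position of miR828, which is known to act on R2R3-MYB transcripts and the TAS4 precursor, held 17031 reads in leaf (454.2 RPM) and 1 read in peel. The peel over leaf ratio was 0.000363 (9.18e-06 to 0.00202 by reads), with an upper bound of 0.0442 on molecule-equivalents. Tags at the cut position of miR858 in the R3 repeat of R2R3-MYB transcripts held 3721 reads in leaf and 0 in peel. They were 6.08-fold lower in peel against a floor of 3 molecule-equivalents, with 4.92-fold as the bound of the 95% interval. Tags of the other 29 families together went the other way, at 404.2 RPM in peel and 243.3 in leaf, a ratio of 1.66 (1.28 to 2.10). Relative to the median of shared tags this last ratio was -1.42 on the log2 scale, so its direction was not settled, while miR828 stayed lower in peel at -13.59. R3-coding tags that started elsewhere were also lower in peel, with 34 reads against 1470 in leaf, a ratio of 0.143 (0.00348 to 0.789), and -4.97 relative to shared tags.

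Among single families in Bangalore blue, miR393, which targets auxin receptor transcripts, had a peel over leaf ratio of 2.29 (1.42 to 3.66). For miR171, which targets GRAS family transcription factors, the ratio was 4.57 (2.87 to 7.24). Relative to shared tags these were -0.96 and 0.04 on the log2 scale, so the direction of miR393 depended on the scaling and miR171 lay near 0. Tags of miR160, which targets auxin response factors, held 732 reads in leaf and 0 in peel, where the upper bound of the ratio was 1.07, so no difference was detectable at this depth. The tag CACCAAGCGAGACCAATGAC, complementary to miR168, held 167 reads in Bangalore blue peel and 0 in the other 3 libraries.

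In Dilkhush the same direction held for both sets of tags. miR828 tags held 207 reads in peel and 11037 in leaf, 12.0 and 308.9 RPM, a ratio of 0.0390 (0.0149 to 0.0892), and in peel they did not exceed the highest other start position, at 16.2 RPM. R3 tags at the miR858 position held 99 and 5522 reads, a ratio of 0.0373 (0.00833 to 0.120). R3-coding tags that started elsewhere had a ratio of 0.491 (0.181 to 1.06). The other 29 families had a ratio of 1.18 (0.963 to 1.42), which was not distinguishable from no change at this depth, and relative to shared tags it was -0.74 on the log2 scale, so its direction was not settled. On that scale miR828 stayed lower in peel at -5.65 and R3 tags at the miR858 position at -5.72.

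Single families in Dilkhush moved both ways. miR403, which targets AGO2, was lower in peel with a ratio of 0.418 (0.242 to 0.671). miR160 tags held 1204 reads in leaf and 0 in peel, 5.35-fold lower in peel against the floor, with 4.19-fold as the bound of the interval. Peel was higher for miR156, which targets SPL factors, with a ratio of 3.23 (2.08 to 5.14), and for miR482, which targets disease resistance transcripts, with a ratio of 5.17 (2.64 to 10.6). Both kept this direction relative to shared tags, at 0.72 and 1.40 on the log2 scale. miR166 was also higher in peel, with a ratio of 8.25 (3.41 to 23.8), and 2.07 relative to shared tags. miR396 was lower, with a ratio of 0.0883 (0.00193 to 0.460), but did not stand out from other start positions in either Dilkhush library. For miR156 the peel reads came almost wholly from TCTTCTGTCAATGAATAAAA, with 1527 reads in Dilkhush peel and 0 in the other 3 libraries. Tags of miR160, miR390 and miR828 stood out from other start positions in both leaves and in neither peel. Standing out needed at least 3 molecule-equivalents, which were 16.3 RPM in Bangalore blue peel. In Bangalore blue leaf miR390 held 11.3 RPM, so at that level it could not have stood out in the peel. miR160, at 19.5 RPM in that leaf, was close to the limit.

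**Figure D3:**
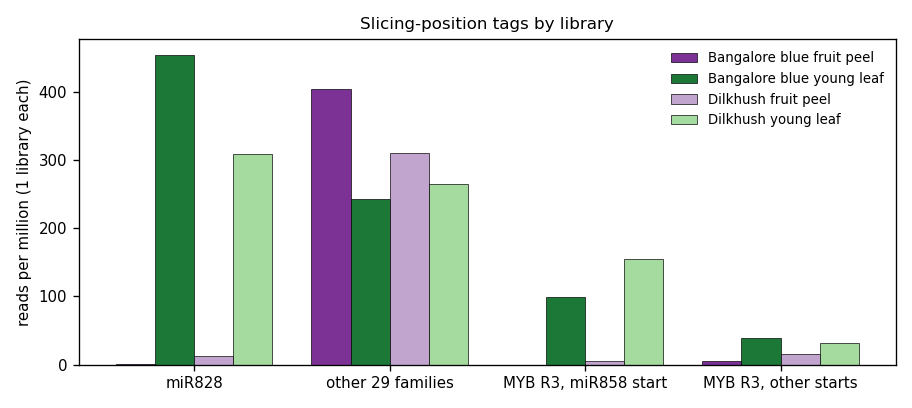
RPM (vertical axis, from 0) of 4 sets of tags in each library, 1 bar per library. The miR828 bars reach 454.2 and 308.9 in the leaves and 0.165 and 12.0 in the peels, while the other families lie between 243.3 and 404.2 in all 4 libraries.

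The 11 supported miR828 tags are given here in full. TTGAGCAAGAAAATGTGGAT was the most abundant, with 12667 reads in Bangalore blue leaf and 3219 in Dilkhush leaf, and 1 read in each peel. TTGAGCAAGAAACTACAACA held 2024 and 3098 reads in the same leaves, TTGAGCAAGAAATTATAAGC 1322 and 1536, TTGAGCAAGAAAATAAAGCA 203 and 247, and TTGAGCAAGAGATTGCAAGC 193 and 218. TTGAGCAAGAGGAGGGTTTC held 34 and 50 reads, and TTGAGCAAGAAACCAAGAGC held 47 and 36. Another 4 tags were each found in the leaf of a single cultivar. Among them, the most abundant in Dilkhush leaf and the most abundant in Bangalore blue leaf differed only at the last base. Whether these are variants of a single site was not tested. TTGAGCAAGAAATTATGGGT held 2462 reads in Dilkhush leaf and 200 in Dilkhush peel, and 0 in both Bangalore blue libraries. TTGAGCAAGAAATTATGGGC held 251 and TTGAGCAAGAACCAAAACAG 128 reads in Bangalore blue leaf only, and TTGAGCAAGAGTACAAGAGT held 51 in Dilkhush leaf only.

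Tags at the miR858 position carried changes from the exact complement of miR858b. With positions counted from 1 at the tag's 5′ end, AGACAATGAAATCAAGAATT carried C7T and held 2744 reads in Bangalore blue leaf and 3445 in Dilkhush leaf. AGACAACGAGATAAAGAATT carried A10G and held 309 and 1559 reads in the leaves and 99 in Dilkhush peel. AGACAATGAAATCAAGAACT carried C7T and held 668 and 329 reads. Another 2 tags at this position were found in Dilkhush leaf only, with 144 and 45 reads. Each of the 5 tags coded for the peptide DNEIKN, and each change leaves a G:U pair with the miRNA. Of the reads of R3-coding tags, 71.7% started at this position in Bangalore blue leaf and 83.3% in Dilkhush leaf, with exact Clopper-Pearson intervals on molecule-equivalents of 67.0 to 76.1 and 78.4 to 87.5. In Dilkhush peel the share was 27.5% of 360 reads (6.67 to 65.3), and in Bangalore blue peel it was 0 of 34 reads. The position held 9342 reads over the libraries, and none of 25 other positions held more than 359. No exact complement of miR858 was supported.

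**Figure D4:**
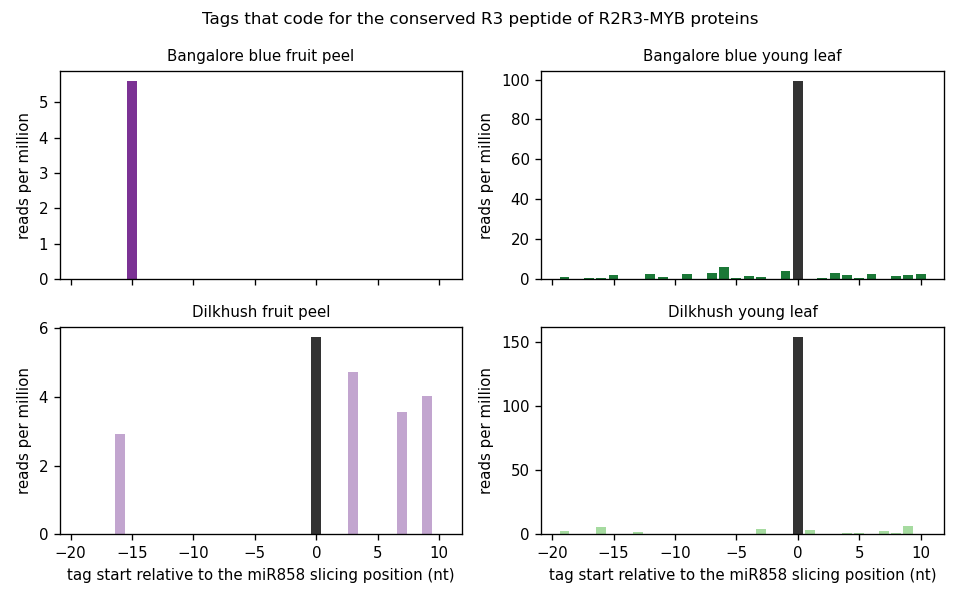
RPM (vertical axis, scaled per panel) of tags coding for the conserved R3 peptide, by tag start relative to the miR858 slicing position (horizontal axis, nucleotides). The dark bar at 0 reaches 99.2 in Bangalore blue leaf and 154.5 in Dilkhush leaf, 5.76 in Dilkhush peel, and is empty in Bangalore blue peel.

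The cultivar comparison in young leaf set Bangalore blue against Dilkhush. miR828 tags were higher in Bangalore blue leaf by 1.47-fold (1.32 to 1.64). That direction rested on TTGAGCAAGAAAATGTGGAT, which held 75.1% of the miR828 reads in Bangalore blue leaf and 29.5% in Dilkhush leaf, and without it the ratio was 0.532 (0.455 to 0.622). Of 7 miR828 tags found in both leaves, 5 were higher by RPM in Dilkhush. R3 tags at the miR858 position were lower in Bangalore blue leaf, with a ratio of 0.642 (0.538 to 0.767), while R3-coding tags elsewhere had a ratio of 1.27 (0.893 to 1.83).

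Among other families in leaf, miR403 had a Bangalore blue over Dilkhush ratio of 0.543 (0.428 to 0.686), miR160 0.579 (0.388 to 0.864) and miR156 0.428 (0.264 to 0.691). miR171 tags held 1141 reads in Bangalore blue leaf and 3 in Dilkhush leaf, a ratio of 362.4 (123.7 to 1760 by reads) with a lower bound of 12.1 on molecule-equivalents. The miR171 reads lay almost wholly in GGCTCAATCAACGGTTGCGA, with 1061 reads in Bangalore blue leaf and 0 in Dilkhush leaf. miR393 had a ratio of 1.45 (1.05 to 2.01). These directions held relative to shared tags. The other 29 families together had a ratio of 0.920 (0.812 to 1.04), which was not distinguishable from no change at this depth.

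The cultivar comparison in fruit peel addressed the tissue where pigment accumulates. Tags at the miR828 position and R3 tags at the miR858 position came to at most 6 molecule-equivalents in each peel. miR828 held 1 read in Bangalore blue and 207 in Dilkhush, a ratio of 0.0137 (0.000345 to 0.0770 by reads), and on molecule-equivalents the Dilkhush over Bangalore blue ratio had a lower bound of 0.454, so no difference was detectable at that depth. miR171 tags were higher in Bangalore blue peel by 11.6-fold (4.53 to 33.4), and by 2.74 on the log2 scale relative to shared tags. miR156 tags held 0 reads in Bangalore blue and 1537 in Dilkhush. They were 5.53-fold lower in Bangalore blue against the floor, with 4.30-fold as the bound of the interval. The tag CCTGGTCCGAGCTCGTCGAC, complementary to miR166, held 676 reads in Dilkhush peel and 0 in Bangalore blue peel. It was not matched to a transcript, so whether it comes from a class III HD-ZIP target of miR166 was not tested. The miR393 and miR403 ratios of 1.59 (0.911 to 2.86) and 0.830 (0.268 to 2.13) were not distinguishable from no change, and relative to shared tags miR393 changed sign to -0.12.

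Among single tags of these families, a miR393 tag was nearly private to Bangalore blue. It differed at 1 base from a miR393 tag found in all 4 libraries. A sequence variant between the cultivars was therefore not told apart from a difference in slicing. TCCCTTTGGATGTCGTCCTG held 579 reads in Bangalore blue peel and 709 in its leaf, and 1 and 0 in the Dilkhush libraries. TCCCTTTGGATGTCATCCTG was found in all 4, with 132, 404, 1204 and 951 reads in the order of the libraries above. For miR403, GTGAATCTAATGGGTTGCTA held 147, 1668, 474 and 3184 reads in that order. The most abundant supported tag of miR160 was GAGCCAGGCAAGATTCTTTC, with 348 and 619 reads in the leaves. For miR390 it was TCCTGAGCTTAGTCTTCTTA, with 419 and 464, and for the TAS3-derived small RNA AGGTCAAGAAAATGTAGGTT, with 133 and 134, beside AGGTCAAGAATGACGTTACG, with 7 reads in Bangalore blue leaf only. The top miR396 tag by RPM was AGCTGTGGAATTTGTTCTTC, with 181 reads in Bangalore blue peel only, and the top miR482 tag was GTAGGAAAGATTTTCGTTAC, with 838 reads in Dilkhush peel. For miR477 it was TGAGGGAGATTATGACAACC, with 128 reads in Bangalore blue peel and 63 in Dilkhush leaf.

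The 3 supported miR159 tags were found in Bangalore blue leaf only. TCAATCCAAATGGGATGACA held 83 reads, TCACTCCAAGTGGAACCCCA 76 and TCAATCCAAAGGTTCCTTAT 45. Of the 4 miR319 tags, TTCAGTCCAAGAGCAATGTA held 80 reads in Bangalore blue peel, TTCAGTCCAAGCCTCGCTGT 28 and TTCAGTCCAATTCTCCGTCT 22 in its leaf, and TTCAGTCCAAAGTGCAAGTG 21 in Dilkhush leaf. The top tags in Bangalore blue leaf were TGCTTCTCCAGCTTATGCAT for miR164 with 111 reads, TCCTTGGCTGTTATTTCCAT for miR169 with 60, CACTCAATGAACAAAATGTC for miR397 with 57 and GGTTTATCGAAATCCACAAG for miR162 with 33. Lower there were CTCGTTGTCAGGGCTAGTGA for miR535 with 24 reads, GGCAGCTTCAAGAAGTAATT for miR167 with 20 and AACACTTCAGCACAAGACAA for miR395 with 9. In Dilkhush leaf they were TCCTTTGGCAACACCACCGC for miR399 with 93 reads, AGAATGCCAACTCATGCAAA for miR394 with 49, TCAAGATTCTCGTTTCACCA for miR172 with 46 and TGAGAACACATTCGGATTCT for miR398 with 23. The slicing position did not stand out from the others in any library for miR162, miR167, miR169, miR172, miR319, miR394, miR395, miR398, miR399 or miR535. No tag was supported for miR408, miR479, miR827 or the exact complement of miR858. These negative results cover exact complements only. Sites with a G:U pair, such as the R3 tags at the miR858 position, are missed by that rule.

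Over all tags, the largest cultivar differences recurred in both tissues for some tags, with all intervals of single tags computed by reads. In peel, GTTCCCGACATTTATCGTCT was higher in Bangalore blue by 10950-fold (6839 to 18800), at 10830 RPM against 0.989, and ACCGGCGCTGATTTTTCTAC by 10850-fold (6682 to 18990). Lower in Bangalore blue peel were ACGTCCAACGATCCGTACCA, with 3 reads against 76832, a ratio of 0.000111 (2.28e-05 to 0.000323 by reads), and TGCTTCAAAAGTTTATTTTC, with 1 read against 23701, a ratio of 0.000119 (3.02e-06 to 0.000665). In leaf, TGCTTCAAAAGTTTATTTTC was again lower in Bangalore blue, with 4 reads against 47686, a ratio of 7.99e-05 (2.18e-05 to 0.000205). AGCAGGCCGTTGATCCACCT held 13 reads in Bangalore blue leaf and 245581 in Dilkhush leaf, a ratio of 5.04e-05 (2.69e-05 to 8.63e-05). Higher in Bangalore blue leaf were GAGAGGTCAGGACTGAACTC, with 23725 reads against 1, a ratio of 22610 (4057 to 893000 by reads), and ACATCCTCATGACAATAGAT, with 39426 against 4, a ratio of 9392 (3668 to 34470). The lower side of each came to 0 or 1 molecule-equivalents, so the read ratios rest on few reads. For the first tag higher in Bangalore blue peel and both lower there, a rarer tag differed only at position 3. Each of these rarer tags had a partner, 1 base away, in the other cultivar only. In peel the rarer tags held 609, 979 and 116 reads, and their partners in the other cultivar's peel 252, 34 and 25. The named tags themselves held 65770 reads in Bangalore blue peel and 76832 and 23701 in Dilkhush peel. By the read-error rule used for slicing tags, the rarer tags therefore count as error copies of the named tags. A sequence variant may still contribute to these folds, but pairs that contain an error copy cannot decide this, and it was not tested. Against the floor of 3 molecule-equivalents the folds were 1724 and 1608 for the tags higher in Bangalore blue peel, 274.2 and 84.5 for those lower there, 314.0 and 521.8 for those higher in its leaf, and 6609 for AGCAGGCCGTTGATCCACCT and 1283 for TGCTTCAAAAGTTTATTTTC, lower in its leaf.

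Between tissues, with intervals again by reads, ACACAAAATCGAGGTACATG was higher in peel in both cultivars, with 6090 reads against 0 in Bangalore blue, at least 966.4-fold, and 8886 against 1 in Dilkhush, a ratio of 18470 (3314 to 729600 by reads). TGTGATCGAGGGGGATGTTT was higher in Bangalore blue peel, with 16804 reads against 4, a ratio of 25930 (10130 to 95200). ATTGGAGGCTGTGTTTTTTA held 5026 reads in Dilkhush peel and 0 elsewhere, 145.5-fold higher than in Dilkhush leaf against the floor. Lower in peel were CCTCTCTGGATCGTCTTTGC in Bangalore blue, with 8 reads against 213128, a ratio of 0.000232 (0.000100 to 0.000457), and CTACGACGGAAGGTACTGGA, with 0 against 27300, 44.7-fold against the floor. In Dilkhush, ATCAGACCCTACTCCAATCT held 5 reads in peel and 29489 in leaf, a ratio of 0.000352 (0.000114 to 0.000823), and GCTTACATAGTCGGTTGCTT 0 and 7033, 31.3-fold lower in peel against the floor. Against the same floor, the tags with reads on both sides came to 256.7-fold for ACACAAAATCGAGGTACATG in Dilkhush, 2659-fold for TGTGATCGAGGGGGATGTTT, 348.7-fold for CCTCTCTGGATCGTCTTTGC and 131.4-fold for ATCAGACCCTACTCCAATCT. The most abundant tag of both leaves was TATTGAAGTGGCAAAGAAGG, at 35140 and 45540 RPM against 5435 and 8944 in the peels of Bangalore blue and Dilkhush.

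Counts of tags beyond 2-fold depended on the counting unit. By reads, among tags with at least 20 reads in a pair of libraries, 39559 were higher and 101653 lower in Bangalore blue than Dilkhush peel, and 295776 higher and 229118 lower in leaf. In peel against leaf, 40610 were higher and 161205 lower in Bangalore blue, and 94606 higher and 264959 lower in Dilkhush. By molecule-equivalents the same 4 comparisons gave 6761 higher and 837 lower, 9964 and 29828, 23519 and 538, and 20644 and 1923. The share higher thus moved from 28.0% to 89.0%, from 56.4% to 25.0%, from 20.1% to 97.8% and from 26.3% to 91.5%. Simulated libraries without any difference, apart from 200 changed tags, gave calls by reads for 49.3%, 29.5%, 41.9% and 49.1% of unchanged tags in the same order. By molecule-equivalents they gave 0.0399%, 0.0458%, 0.343% and 0.110%. The simulation took the preferred number as the copies per molecule, so the contrast between the units was built in. These rates do not measure false calls in the data. Among the simulated calls without a difference the share higher was 30.7%, 58.1%, 28.4% and 31.4% by reads. By molecule-equivalents it was 100%, 5.97%, 100% and 99.0%. The split between higher and lower can thus follow depth in both units and is no measure of direction.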

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

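Molecule-equivalents, the error rules, G:U pairs and all alternatives on log2 ratios were tests chosen after the data were seen. Of 56 alternative tag counts 38 stayed within 1.5 times, as did 24 of 35 site counts. Of 30 log2 ratios 16 kept their sign and stayed inside their interval. In the order higher and lower for cultivars in peel, cultivars in leaf, tissues in Bangalore blue and tissues in Dilkhush, molecule-equivalents gave 6761, 837, 9964, 29828, 23519, 538, 20644 and 1923 tags. Thinning gave 66266 lower in peel between cultivars, 38640 higher and 41853 lower in leaf, 51274 lower between Bangalore blue tissues, and 59725 higher and 50942 lower between Dilkhush tissues, as fewer reads were counted. A minimum of 50 reads gave 127274 higher and 123837 lower in leaf and 141170 lower between Dilkhush tissues, as fewer tags were tested. Median-of-ratios scaling gave 347835 lower between Bangalore blue tissues. Supported sites in Bangalore blue peel and leaf and Dilkhush peel and leaf came to 20, 164, 37 and 101 with a start within 1 nucleotide, where 9 bases had to match, and to 22, 204, 36 and 112 with a G:U pair. For miR828 and miR858 together these settings gave 27 and 30, and 18 without removal of read errors, against 11. For miR828 between leaves, the log2 ratio of 0.56 became 0.78 with median-of-ratios scaling and -0.91 without the most abundant tag. For the other families, median-of-ratios scaling reversed every comparison, to -0.41 and 0.10 between cultivars in peel and leaf and to -1.42 and -0.74 between tissues in Bangalore blue and Dilkhush. Without their most abundant tag they came to 0.86, 0.18, 0.31 and 0.69 in that order, of which the leaf value reversed. With a G:U pair they reversed to 0.0044 in leaf and to -0.12 and -0.31 between tissues. R3 tags at the miR858 position between leaves came to -1.16 without their most abundant tag. Where no construction is named, the cause was not tested. The peel against leaf log2 ratios in Dilkhush of miR828, between -5.65 and -4.19, and of R3 tags at the miR858 position, between -5.72 and -3.34, kept their direction under every alternative run on them. Splitting shared tags among genes, distinct tags per gene, target scores of 3 or 5, category 0 and all alternatives for flavonoid genes were not run, since no transcripts were used. No paired analysis was made: the labels carry no replicate numbers, and the tissue difference within each of 2 cultivars is given by itself. Depth limits the peels most, since 3 molecule-equivalents were 16.3 RPM in Bangalore blue peel and 6.28 in Dilkhush peel.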

Other observations

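The tests on miR828 in peel, on reads per tag and on cultivar tags were chosen after the result was seen, and those on TGTANATA were written before.

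Tags began 3 nucleotides before TGTANATA, a sequence of the kind bound by Pumilio proteins, in all 4 libraries. Among tags with at least 10 reads, 94 in Bangalore blue peel, 708 in its leaf, 247 in Dilkhush peel and 623 in its leaf had this start, against medians of 8, 103.5, 27 and 81.5 at the other starts. Base composition was argued against by arrangements of the same bases: 0.714% of 140, the sequence itself alone, reached its excess of 7.53, and the next reached 4.90. A ligation preference for the first 3 bases was argued against by an excess of at least 6.64 within classes of those bases. A stop of decay at a bound protein is a candidate explanation that these data did not test.

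Tags of GTCGGA and GTTGGA, whose complement is recognised by the enzyme MmeI, were also unevenly placed. GTTGGA 4 nucleotides into the tag was found in 87, 946, 266 and 618 tags, at least 4.23 times its median position in each library, and GTCGGA at 5 nucleotides in 48, 429, 114 and 283. AACCAC was found at the tag start in 23, 231, 180 and 338 tags, at least 3.55 times its median position. Other sequences without the MmeI site were placed about as unevenly. GTTCGG 3 nucleotides into the tag reached at least 4.25 times its median position in each library, and CGGGCT at 6 nucleotides at least 4 times. Both share the bases CGG with GTCGGA, so they are not independent of the site. These counts therefore cannot tell whether the uneven placement was particular to it.

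Tags of miR828 were nearly absent from fruit peel. Depth was argued against, since the leaf share predicted 83.6 molecule-equivalents in Bangalore blue peel and 147.5 in Dilkhush peel, where 0 and 6 were seen. A loss of slicing tags in every family was argued against by the other families, whose lower pooled peel over leaf ratio was 1.18. It was also argued against by miR393, at 2.29 in Bangalore blue and 2.08 in Dilkhush. A loss shared by some families stays open. In Dilkhush peel miR160 (0 reads against 1204) and miR403 (a ratio of 0.418) were also lower. So was miR390, with 3 reads against 469 and an upper bound of 0.63 for the ratio on molecule-equivalents. miR396 fell as well, with 41 reads against 965, but did not stand out from other start positions in either Dilkhush library. miR156, miR166, miR171, miR393 and miR482 were higher in Dilkhush peel. Of the 5345 pooled peel reads in Dilkhush, 1527 were of a single miR156 tag. With median-of-ratios scaling the pooled families came to -1.42 and -0.74 on the log2 scale in Bangalore blue and Dilkhush. miR393 came to -0.96 and 0.09, so whether they rose is open, but miR828 moved by as much, to -13.59 and -5.65. The value of -13.59 rests on 1 read in Bangalore blue peel. Before that scaling, the upper bound of this miR828 ratio on molecule-equivalents was 0.0442. Fewer transcripts of the miR828 targets, such as R2R3-MYB genes, or lower miR828 activity in peel may each account for the pattern: R3-coding tags outside the miR858 position had peel over leaf ratios of 0.491 in Dilkhush and 0.143 in Bangalore blue, but no miR828 tag was matched to a transcript, and small RNA levels were not analysed here.

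Reads per tag piled up at a preferred number in each library. Sequencing errors of abundant tags were argued against, since tags at that number lay 1 mismatch from an abundant tag at most 0.114 times as often as tags with 1 to 4 reads. Amplification copies of single molecules are consistent with a second maximum at a median of 1.92 times the first in 3 of 4 libraries. Bangalore blue leaf had no separate second maximum, so its molecule-equivalents are the least sure. No biological explanation was tested.

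Some tags were specific to a cultivar in both tissues, 3771 to Bangalore blue and 8261 to Dilkhush, with at least 20 reads in each library of the cultivar and at most 1 in the others. Crossed pairs of libraries gave 1506 and 7800 such tags and the tissues 1684 and 45930, so the counts by themselves do not set the cultivars apart. Among the tags specific to a cultivar 115 pairs differed by 1 base, of which 111 remained without read-error copies, and these held 77 distinct base changes once overlapping tags were counted together, against 3 that separated the tissues and 1 that separated crossed pairs of libraries, which may reflect sequence variants between the cultivars. With positions from 1 at the 5′ end, ATAATGTTGGCTGTGTACTT held 349 and 3864 reads in Bangalore blue peel and leaf, and its partner ATAATGTTGGTTGTGTACTT, with C11T, held 1599 and 656 in Dilkhush. TCTCTAGTCCATTTGAATAG held 2262 and 135 reads in Bangalore blue, and its partner TCTCTAGTCCACTTGAATAG, with T12C, held 1706 and 433 in Dilkhush.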
